A study of Caenorhabditis elegans with 15 samples.

How the data were processed

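RNA from whole Caenorhabditis elegans (wild-type strain N2, kept at 20 °C on agar seeded with OP50 bacteria) was measured on a single-channel Affymetrix expression array, with 1 hybridisation per biological replicate. Worms were exposed for their whole life and collected on day 1 of adulthood. The labels give 5 groups of 3 replicates: a water control, a Z-medium control, filtrate of Lake Stößensee from August, filtrate of the same lake from October, and filtrate of a batch culture of the cyanobacterium Microcystis aeruginosa. Z-medium stands in the labels as the control of the culture, and water as the control of the lake samples. AOBr, adsorbable organic bromine in the usual reading of the abbreviation, was the measure by which the samples were dosed, at 200% of the original content for the lake samples and 40% for the culture. The lake and culture samples were filtered (and lyophilised) before use, and the labels do not say whether water and Z-medium were treated alike. The labels give no date, plate or hybridisation batch.

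The deposited values are linear probe set signal intensity, made per the submitters' processing notes with the MAS5 algorithm in Affymetrix Expression Console 1.2.0.20. The mean of each array after trimming 2% of the probe sets at each end lay between 500.123 and 500.137, so each array had been scaled to 1 common level. Every signal was positive, from 0.0335 to 34065. The table held 22625 probe sets on 15 arrays, no column of another series, and no detection calls. Raw scan files were not analysed here. For arrays, precision is limited by their number, here 3 per group.

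Signals were taken to log2 with no offset and no further scaling. The 77 control probe sets were left out of the tests, and of the other 22548 the 13529 with a mean log2 signal at or above the 40th percentile (5.86, or a linear signal of 57.9) were tested. Gene names came from the array annotation and a table of current gene symbols: 20766 probe sets had exactly 1 symbol, of which 20701 matched a gene ID of that table, 887 had several symbols and 895 none. No genome build is named for the array, so no coordinates are given.

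All 15 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes with an intensity trend, 10 residual degrees of freedom), and each comparison was a contrast of group means. P values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set counted as higher or lower at an adjusted p under 0.05. Errors given with log2 changes are the standard errors of that model, and errors given with signals are standard deviations over 3 arrays. The deposited values give no background, so where a group mean lay below the filter a change that passed is given as at least the size it has with that mean set at the filter level. Fold changes come from the log2 means, so they can differ slightly from the ratio of the mean signals. The 3 main comparisons were August lake water against water, October lake water against water, and M. aeruginosa culture against Z-medium. The others were October against August, Z-medium against water, and the culture effect minus the mean lake effect, which tests the difference of the effects itself. With 3 arrays against 3, an exact permutation test of 1 probe set cannot give a p below 0.1, so none is printed.

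Gene lists numbering 38, covering detoxification, stress, immunity, reproduction, cuticle, metabolism, nerve, muscle and housekeeping functions, were tested with camera from limma at a preset inter-gene correlation of 0.01, with 1 probe set per gene (10259 genes), adjusted over the 38 lists and the 3 main comparisons together, and for each other comparison over its own 38 lists. An estimated correlation per list and the rotation test fry were run beside it with statmod 1.5.0 installed. Counts of list members past the test were made on the brightest probe set of each gene, adjusted over all 13529 probe sets and also over the list alone. Genes that passed only on another probe set are named beside them. The lists, the tests, the filter, the alternatives not named as later and the rule for named genes were fixed before the data were examined.

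Genes are named by rule: per main comparison, the 10 largest rises and 10 largest falls among probe sets with 1 symbol that passed the test with no overlap between the arrays of both groups, filled by the smallest p where fewer passed, and up to 4 members of each list past the list test or with a member past the gene test. The other comparisons used 5 and 5. Named genes whose function was not known were counted and may be left out of the text. This named 34 genes for August (1 past the test), 24 for October (0 past it in limma; 286 probe sets had an unadjusted p under 0.05, where chance gives 676), 115 for the culture (62), 10 for October against August (2), 10 for Z-medium against water (1) and 10 for the culture effect minus the lake effect (10). Here and below, 676 assumes evenly spread p values. The model held no replicate term, so a difference of replicate 1, present in each group, stayed in the residual spread. A count below 676 can come from this and does not show fewer changes than chance.

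Whether replicate numbers pair the arrays was checked by correlating each array's deviations from its group mean with those of the same number in the other group. These correlations lay between 0.200 and 0.534 for August and water, between 0.0644 and 0.467 for October and water, and between -0.0325 and 0.357 for culture and Z-medium. They lay between 0.214 and 0.457 for October and August and between 0.209 and 0.563 for Z-medium and water. With every correlation over 0.1 as the rule, the numbers were read as pairs for August and water, for October and August and for Z-medium and water. Blocked values are given where the block changed a call or a count. In 10 of the 15 arrays the deviations correlated best, on average, with arrays of the same number.

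The model was tested on simulated data with the residual spread of the 13529 probe sets, of which 67, 67 and 66 were altered in each comparison. In the August simulation it recovered 29.9%, 74.6% and 95.5% of changes of 0.5, 1 and 2 on the log2 scale, with 1 false call among 134. In the October simulation the shares were 29.9%, 80.6% and 98.5%, with 3 false calls among 142. In the culture simulation they were 31.3%, 79.1% and 100%, with 14 false calls among 154. When the P450 list was raised by 0.3 in the culture simulation it was called with the preset and with the estimated correlation, and 0 of the other 37 lists were called (camera). The simulated spread was independent between probe sets and arrays. Its size came from a fit without a replicate term, so it held the spread due to replicate 1 but not its pattern over arrays. The simulation therefore cannot show how often lists are falsely called, or missed, where genes vary together as on the real arrays.

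Alternatives fixed in advance were quantile normalization, scaling to a common median, offsets of 16 and 64, no filter, a filter at the 60th percentile, no intensity trend, robust fitting, a fit of the compared groups alone, replicate number as a block, an adjusted p under 0.10, array weights, fry, an estimated correlation, and leaving out each array in turn. A term for replicate 1, leaving out the 5 replicate 1 arrays, a covariate for position along the replicate 1 difference, and list tests with both the block and an estimated correlation were added after the arrays had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.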

Results

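Transcript levels were measured in whole day 1 adult worms on 15 arrays, 3 in each of 5 groups. The median signal of an array lay between 99.2 and 113, and the log2 signals of arrays of 1 group correlated across probe sets at 0.975 to 0.990. The arrays did not differ by group alone. The first principal component, which held 38% of the variance, put the replicate 1 arrays of water, Z-medium, August and October at -28.9 to -21.8. All other arrays lay at -0.20 or above, with the culture arrays at 11.96, 26.7 and 36.1, replicate 1 the lowest of these. By limma, 2451 of 13529 probe sets differed between replicate 1 and replicates 2 and 3 across all groups (1455 higher and 996 lower in replicate 1). Between replicates 3 and 2, fitted on their own arrays alone and so with less power, 0 passed. There 1181 had an unadjusted p under 0.05, where chance gives 676, so a smaller difference between these replicates is not excluded. In the 9 lake and water arrays the median of the sperm list was 0.52 higher on the log2 scale in replicate 1 than in replicates 2 and 3. The cuticle collagen list was 0.34 higher, the molting list 0.29 higher and the oocyte and eggshell list lower (log2 difference -0.11). The labels name no batch for these arrays, and each group held 1 of them.

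The August lake sample was compared with water to find which transcripts differ in worms raised with it. The labels describe filtration and lyophilisation for the lake and culture samples and do not say whether the controls were treated alike, so a difference from a control may include an effect of that handling. A single gene passed the test: cyp-33A1, a member of the cytochrome P450 family of monooxygenases, whose signal rose from 258 ± 28.8 in water to 2561 ± 107 (SD, n = 3). This was a 9.94-fold rise (log2 change 3.31 ± 0.12, SE; limma adjusted p = 2.32e-10). All 3 August arrays lay above all 12 others for this gene, with mean signals of 252 in Z-medium, 246 in October and 237 in the culture. The next gene by p, fat-7, a stearoyl-CoA desaturase that makes oleic acid, had a signal of 3924 ± 386 against 2361 ± 88.1 in water (log2 change 0.73 ± 0.12). It was higher in 3 of 3 arrays but did not pass (adjusted p = 0.139). With replicate number as a block, since the rule read these numbers as pairs, fat-7 passed with the same log2 change (adjusted p = 0.00368; between 0.00368 and 1.00 over 10 alternative settings) and the count became 2. Other named genes that did not pass included ugt-2 (log2 change 0.81 ± 0.24), cyp-13A2 (0.75 ± 0.22) and warf-1 (-0.67 ± 0.17), each with an adjusted p of 1.00.

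**Figure D1:**
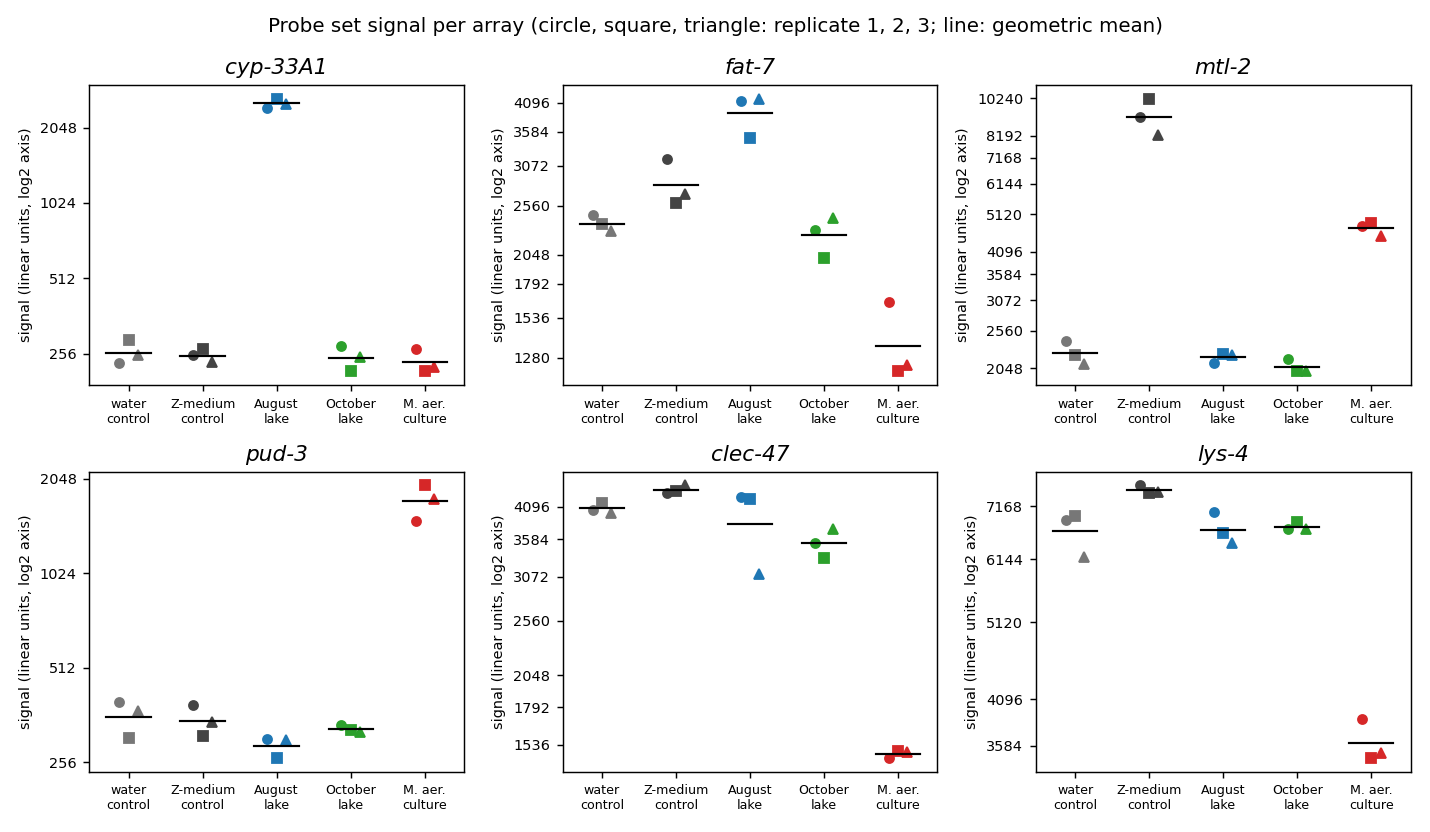
Probe set signal of 6 genes on each of 15 arrays, by group, in linear units on a log2 axis that does not start at 0. Circles, squares and triangles are replicates 1, 2 and 3, and lines are geometric means. The cyp-33A1 signal lies between 2462 and 2675 on the August arrays and at 290.1 or below on all others, and the mtl-2 signal is highest in Z-medium.

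The cytochrome P450 list was called higher in August: of 36 genes tested, 1 rose, cyp-33A1, 0 fell and 35 did not pass. The list was not tested without cyp-33A1, so its call may rest on that gene. A positive change was seen in 24 (median log2 change 0.07; camera adjusted p = 0.0183; adjusted p = 0.451 with an estimated correlation). Adjusted over the list alone, the same number, 1, rose. The ribosomal protein list was shifted upward by a median of 0.08 with 67 of 74 genes positive (adjusted p = 4.22e-09; adjusted p = 0.763 with an estimated correlation). The proteasome list was shifted by 0.07 with 24 of 33 positive (adjusted p = 0.00124; adjusted p = 0.763 with an estimated correlation). For the oocyte and eggshell list, 16 of 18 genes were positive with a median of 0.07 (adjusted p = 0.00498; adjusted p = 0.763 with an estimated correlation). In these 3 lists 0 genes passed in limma, over all genes or adjusted over the list alone, while 412 of the 13529 probe sets tested had an unadjusted p under 0.05, where chance gives 676. Quantile normalization ended the ribosomal protein call (adjusted p = 0.878, median 0.00) and the oocyte and eggshell call (adjusted p = 0.149). Without water replicate 1 the P450 (adjusted p = 0.344), proteasome (0.129) and oocyte (0.652) calls ended, without August replicate 3 the proteasome (0.353) and oocyte (0.694) calls, and without August replicate 2 the P450 call (0.206). The P450 call also ended without the 5 replicate 1 arrays (adjusted p = 0.260). With the replicate block the molting list, at a median of -0.09, was also called lower (adjusted p = 0.0386, against 0.103 without the block; adjusted p = 0.735 with the block and an estimated correlation).

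The October sample was compared with water to ask the same question later in the season. No gene passed in limma (0 of 13529, smallest adjusted p = 0.130). An unadjusted p under 0.05 was found for 286 probe sets, against 676 for evenly spread p values. The replicate 1 difference in the residual spread can lower this count, so it does not show fewer changes than chance. With replicate number as a block, though the rule did not read these numbers as pairs, drd-10 and warf-1 passed (adjusted p = 0.0271 each, up to 1.00 under other settings). The sperm list was then called higher (adjusted p = 0.0124, against 0.259 without the block; adjusted p = 0.735 with the block and an estimated correlation). The named genes with the smallest p were drd-10, with a log2 change of 1.36 ± 0.21 (adjusted p = 0.130), and cnc-2, a caenacin antimicrobial peptide gene, with 1.03 ± 0.19 (adjusted p = 0.494). The lysozyme gene lys-10 had a value of 1.01 ± 0.21 (adjusted p = 0.851). Among those with lower signals were warf-1 (log2 change -0.85 ± 0.17, adjusted p = 0.648), ugt-62 (-0.30 ± 0.08) and the infection response gene irg-5 (-0.41 ± 0.11), the last pair with an adjusted p of 1.00. For each of these genes the 3 October arrays did not overlap the 3 water arrays, as was so for 7.56% of all probe sets, where chance gives 10%. Ribosomal protein genes were shifted downward as a list, with 16 of 74 positive and a median log2 change of -0.03 (adjusted p = 0.00314; adjusted p = 0.913 with an estimated correlation). Of them, 0 passed in limma, adjusted over the list alone or over all genes. That call ended under quantile normalization (adjusted p = 0.143), without water replicate 2 (0.788) and without October replicate 2 (0.149). The P450 list had 1 gene and the lysozyme and antimicrobial list 2 genes that were higher when adjusted over the list alone, with 0 over all genes.

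The M. aeruginosa culture was compared with Z-medium, its own control, to find which transcripts differ in worms raised with a cyanobacterial culture. It gave 209 probe sets past the test of 13529, 48 higher and 161 lower, or 43 genes that rose and 143 that fell. A 2-fold change or more was reached by 12 of the higher and 58 of the lower ones, or by 12 and 49 with group means below the filter set at its level. The gene with the largest rise, pud-3, went from a signal of 347 ± 39.0 to 1745 ± 224 (SD, n = 3; 5.01-fold; log2 change 2.33 ± 0.13; limma adjusted p = 1.11e-07). A gene of the same name family, pud-4, rose 4.88-fold (log2 change 2.29 ± 0.21, adjusted p = 1.09e-05). Further rises were those of irg-4, an infection response gene (log2 change 1.19 ± 0.17, adjusted p = 0.00130), and asah-1, an acid ceramidase gene (1.12 ± 0.13, adjusted p = 2.02e-04). Among the falls, W08E12.2 went from a signal of 125 ± 52.8 to 10.9 ± 2.75, a level below the filter, so its fall was at least 2.05-fold (adjusted p = 2.14e-04). The gene warf-1 fell at least 4.30-fold (adjusted p = 2.93e-06), and dpy-9, a cuticle collagen gene, at least 2.21-fold (adjusted p = 5.23e-04), both to signals below the filter (55.6 and 37.5).

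The 3 culture arrays lay wholly above or below the 3 Z-medium arrays for all 209 probe sets, and for 19.1% of all tested, where chance gives 10%. Median scaling of the arrays shifted the median of all probe sets by 0.11 on the log2 scale and gave 168 calls, 149 of the 209 among them, and 36.9% of the 168 were higher, against 23% with the deposited scaling. It ended the calls of 13 of the 62 named genes (highest adjusted p = 0.168), among them tni-1, metr-1, mtrr-1 and cpr-5. The count fell to 117 when the culture and Z-medium arrays were fitted without the other groups, and to 89 without Z-medium replicate 1, 92 without Z-medium replicate 2, 92 without culture replicate 2 and 100 without culture replicate 3. It was 534 without the 5 replicate 1 arrays, with 174 of the 209 among them, and 1245 with replicate number as a block, with all 209 among them. Of the 62 named genes past the test, 27 stayed past it with each of the 6 arrays left out, 35 did not (highest adjusted p = 0.191), and 0 changed sign. Below, a gene's adjusted p without 1 array is the highest of the 6 such fits. The call ended in 5 of these fits for ugt-9, spp-1, fat-3, metr-1, col-88, tni-1 and dod-3. It ended in 4 for ptr-23, in 3 for col-65, mtrr-1 and hsp-12.3, and in 2 for ins-35 and dhs-26.

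Gut protease, lysozyme and C-type lectin lists were lower in the culture. Of 17 gut protease genes tested, 6 fell and 11 did not pass (median log2 change -0.24; camera adjusted p = 1.31e-06; adjusted p = 0.376 with an estimated correlation). Adjusted over the list alone, 10 fell and 1 rose. The cathepsin B-like protease genes cpr-4 (log2 change -0.97 ± 0.08, adjusted p = 5.10e-06) and cpr-1 (-0.72 ± 0.08, adjusted p = 1.22e-04) and the aspartic protease gene asp-12 (-1.32 ± 0.13, adjusted p = 2.34e-05) were among them. In the lysozyme and antimicrobial list 3 of 38 genes fell, 1 rose and 34 did not pass (median -0.21; adjusted p = 7.16e-04; adjusted p = 0.763 with an estimated correlation). There were 7 falls and 2 rises adjusted over the list alone. The lysozyme gene lys-4 went from 7514 ± 88.5 to 3613 ± 227 (log2 change -1.06 ± 0.07, adjusted p = 2.13e-07). The log2 changes of lys-6 and lys-2 were -1.06 ± 0.13 and -0.73 ± 0.10, while spp-1, a saposin-like antimicrobial gene, rose by 0.48 ± 0.11 (adjusted p = 0.0386, or 0.139 without culture replicate 2). Of 77 C-type lectin genes 8 fell, 0 rose and 69 did not pass, and adjusted over the list alone 10 fell and 1 rose (median -0.17; adjusted p = 0.0133; adjusted p = 0.451 with an estimated correlation). The lectin gene clec-47 fell from 4391 ± 71.4 to 1482 ± 24.2 (log2 change -1.57 ± 0.10, adjusted p = 1.97e-07), and clec-265 and clec-65 had log2 changes of -0.71 and -0.57. A dimmer probe set of clec-65 did not pass (-0.45, adjusted p = 0.0689), and clec-57 passed on 1 of 2 probe sets (-0.81, adjusted p = 0.0309), not the brightest (-0.03). The lectin list's call ended under quantile normalization (adjusted p = 0.0550), without a filter (0.199), without Z-medium replicate 2 (0.0552) and without the replicate 1 arrays (0.0558). It also ended with replicate number as a block (0.0590) and with a term for replicate 1 (0.0507).

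Detoxification genes moved in both directions. Among 36 P450 genes, 2 rose, 1 fell and 33 did not pass, and adjusted over the list alone 5 rose and 1 fell (median 0.12; camera adjusted p = 0.0120; adjusted p = 0.451 with an estimated correlation). The gene cyp-35C1 rose by 0.83 ± 0.14 on the log2 scale (adjusted p = 0.00795, while its other probe set at 0.64 did not pass, adjusted p = 0.0609). The gene cyp-35A2 rose by 0.68 ± 0.15 (adjusted p = 0.0343). Its call ended with each of the 6 arrays left out (up to 0.114, without Z-medium replicate 1) and under quantile normalization (0.0554). In contrast, cyp-33C8 fell by 1.14 ± 0.18 (adjusted p = 0.00315). The value for cyp-33A1 in the culture was -0.09 ± 0.12, which did not pass (adjusted p = 0.757). Of 44 UDP-glucuronosyltransferase genes 2 rose and 2 fell, with 2 and 6 adjusted over the list alone, and the list did not pass (adjusted p = 0.0550). The log2 changes of ugt-62 and ugt-19 were -1.09 ± 0.08 and -1.54 ± 0.20, while ugt-9 rose by 1.07 ± 0.22 (adjusted p = 0.0232, or 0.101 without culture replicate 2). The omega-class glutathione S-transferase gene gsto-1 (log2 change -0.86 ± 0.14) was the 1 of 25 genes of its list that passed. A P-glycoprotein transporter gene, pgp-9 (-1.13 ± 0.17), was 1 of 2 falls among 40 ABC transporter genes. The counts adjusted over the list alone were also 1 and 2. These lists did not pass (adjusted p = 0.579 and 0.464).

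Fatty acid synthesis and methionine cycle genes were lower as lists. Of 19 fatty acid synthesis genes 1 fell, 1 rose and 17 did not pass (median log2 change -0.19; camera adjusted p = 0.00829; adjusted p = 0.451 with an estimated correlation). The desaturase gene fat-7 fell by 1.06 ± 0.12 on the log2 scale (adjusted p = 1.98e-04). In contrast, fat-3, which encodes a desaturase of polyunsaturated fatty acids, rose by 0.54 ± 0.11 (adjusted p = 0.0250, or 0.0871 without culture replicate 3). The list had 3 falls and 1 rise adjusted over the list alone, and its call ended without Z-medium replicate 3 (adjusted p = 0.0672). Of 14 methionine cycle genes 2 fell and 12 did not pass, with 4 falls adjusted over the list alone (median -0.18; adjusted p = 0.00193; adjusted p = 0.716 with an estimated correlation). They were metr-1, the methionine synthase gene (log2 change -0.38 ± 0.09, adjusted p = 0.0491, or 0.186 without culture replicate 3), and mtrr-1, its reductase (-0.42 ± 0.08, adjusted p = 0.0132, or 0.0714 without Z-medium replicate 1). The fatty acid oxidation list did not pass (adjusted p = 0.971): 3 of 37 genes fell, 1 of them the acyl-CoA oxidase gene acox-1.5 (log2 change -0.80), and adjusted over the list alone 3 fell and 1 rose. Its median of 0.03 was positive while the mean and the test pointed down. Of 9 lipase genes 1 fell, also adjusted over the list alone (list adjusted p = 0.325), and atgl-1 rose on 1 of 3 probe sets (0.71, adjusted p = 0.0107), not the brightest (0.08).

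As lists, by camera at the preset correlation, cuticle collagen, molting and sperm genes were lower in the culture and oocyte and germline genes higher, while few or none of their members passed over all genes. Of 104 cuticle collagen genes 8 fell, 0 rose and 96 did not pass (median log2 change -0.46; camera adjusted p = 2.55e-12; adjusted p = 0.763 with an estimated correlation), and adjusted over the list alone 48 fell. Besides dpy-9, these included col-65 (log2 change -1.86 ± 0.39, adjusted p = 0.0250, or 0.103 without Z-medium replicate 2) and col-88 (-1.62 ± 0.35, adjusted p = 0.0321, or 0.149 without Z-medium replicate 1). The collagen gene bli-1 passed only on the dimmer of 2 probe sets (adjusted p = 0.0418; -0.91 and adjusted p = 0.234 on the brighter). Of 51 molting genes 1 fell on its brightest probe set, ptr-23, of a patched-related family (log2 change -0.79 ± 0.17, adjusted p = 0.0278, or 0.132 without culture replicate 2). Its other 3 probe sets, at -0.53 to -0.47, did not pass. The molting gene mlt-9 also fell, on the dimmer of 2 probe sets (adjusted p = 0.0205; -1.28 and adjusted p = 0.0692 on the brighter). Adjusted over the list alone 6 fell (list median -0.29; adjusted p = 7.54e-05; adjusted p = 0.763 with an estimated correlation). None of 51 sperm genes passed (0 in limma, over all genes or adjusted over the list alone), 47 were negative and the median was -0.44 (adjusted p = 2.40e-07; adjusted p = 0.763 with an estimated correlation). The 18 oocyte and eggshell genes were all positive with a median of 0.15 (adjusted p = 3.31e-05; adjusted p = 0.763 with an estimated correlation). Of 29 germline mitosis and meiosis genes 26 were positive with a median of 0.10 (adjusted p = 0.00193; adjusted p = 0.763 with an estimated correlation). In both lists 0 genes passed in limma, also adjusted over the list alone, in a comparison in which 2063 of 13529 probe sets had an unadjusted p under 0.05. The germline call ended without Z-medium replicate 1 (adjusted p = 0.0589).

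In these 5 lists the medians of replicate 1 against replicates 2 and 3 in the lake and water arrays were opposite in sign to the culture change. They were 0.34 for collagen, 0.29 for molting, 0.52 for sperm, -0.11 for oocyte and -0.12 for germline genes. Across the tested probe sets, which are not independent replicates, the culture change correlated with that replicate 1 difference at r = -0.604 (rho = -0.544), and 79.4% of the 209 calls were opposite in sign to it. Without the 5 replicate 1 arrays 41 collagen, 6 molting and 14 sperm genes fell, and 0 oocyte and 0 germline genes rose in limma. With a term for replicate 1 the counts were 53, 13, 25, 2 and 1, so the numbers of members past the test depend on how the replicate 1 difference is modelled. The 5 lists kept their calls without those arrays. With the block and an estimated correlation none of them passed in camera. The adjusted p was then 0.0678 for collagen, 0.269 for sperm, 0.291 for germline, 0.544 for molting and 0.629 for oocyte genes.

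**Figure D2:**
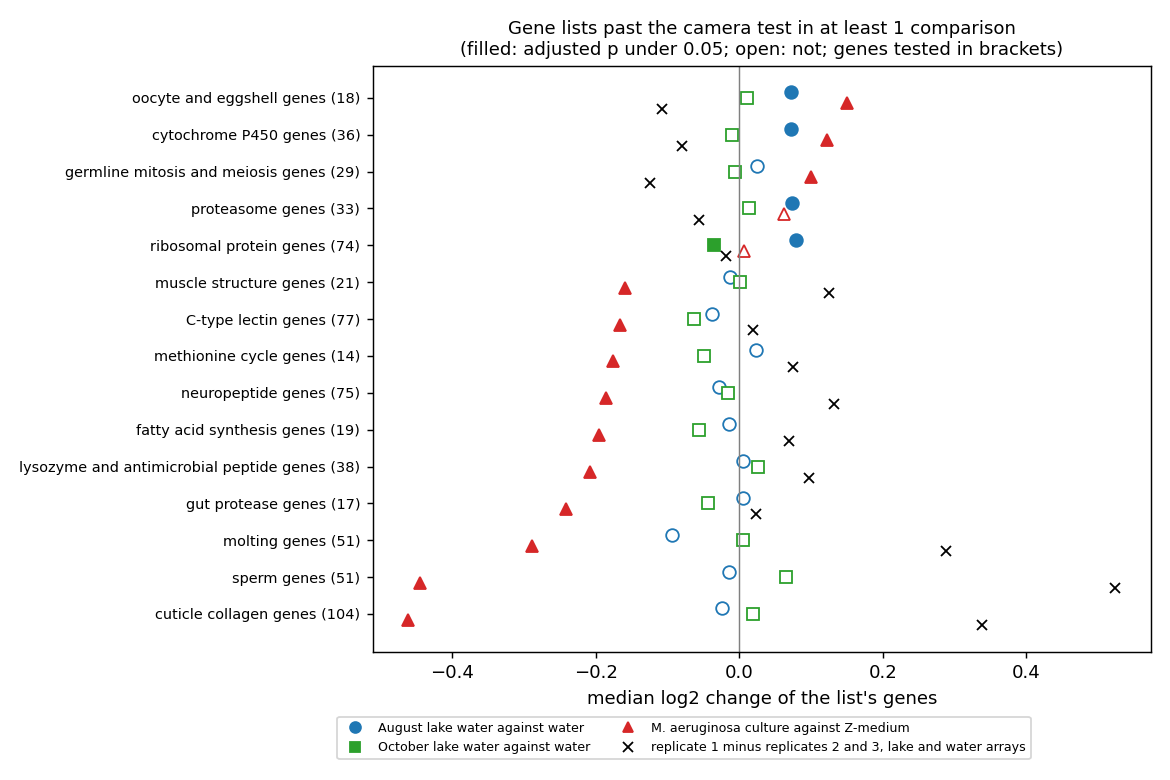
Median log2 change of each gene list past the camera test in at least 1 main comparison, with the number of genes tested in brackets. Filled symbols passed (adjusted p under 0.05) and crosses give replicate 1 minus replicates 2 and 3 in the lake and water arrays. Collagen and sperm lists sit at -0.46 and -0.44 in the culture and at 0.34 and 0.52 between replicate numbers.

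Neuropeptide and muscle lists were lower in the culture too. Of 75 neuropeptide genes 2 fell and 73 did not pass, with 6 falls adjusted over the list alone (median log2 change -0.18; camera adjusted p = 7.16e-04; adjusted p = 0.763 with an estimated correlation). The insulin-like gene ins-35 fell at least 1.22-fold, to a signal below the filter (23.3; adjusted p = 0.0147, or 0.0630 without Z-medium replicate 1). The list's call ended without the replicate 1 arrays (adjusted p = 0.130). Of 21 muscle structure genes 1 fell, tni-1, a troponin I gene (log2 change -0.54 ± 0.12, adjusted p = 0.0341, or 0.171 without Z-medium replicate 1). There were 4 falls adjusted over the list alone (list median -0.16; adjusted p = 0.00208; adjusted p = 0.763 with an estimated correlation), and this call ended without culture replicate 3 (adjusted p = 0.167). In the lake and water arrays the medians of replicate 1 against replicates 2 and 3 were 0.13 for both lists. Scaling moved the medians of 11 of the 13 lists past the test in the culture by more than 1.5 times. The neuropeptide median was -0.10 under quantile normalization and -0.07 under median scaling, and the lectin median -0.06 under both. Median scaling, which moves every probe set alike, put muscle at -0.05, methionine cycle at -0.07, fatty acid synthesis at -0.08, lysozyme at -0.10, gut protease at -0.13 and molting at -0.18. It put P450 at 0.23, oocyte at 0.26 and germline at 0.21. No list past the test changed the sign of its median.

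The remaining lists with a member past the test did not pass themselves. Of 24 antioxidant genes msra-1, a methionine sulfoxide reductase gene, fell (log2 change -0.83 ± 0.13, adjusted p = 0.00328; list adjusted p = 0.403). Of 7 metal response and iron genes mtl-2, a metallothionein gene, fell (log2 change -0.96 ± 0.08, adjusted p = 5.10e-06; list adjusted p = 0.601). Of 26 short-chain dehydrogenase genes dhs-26 rose (1.34 ± 0.26, adjusted p = 0.0142, or 0.0802 without culture replicate 2; list adjusted p = 0.637). Of 9 DAF-16 activated genes dod-3 rose (0.75, adjusted p = 0.0295, or 0.128 without culture replicate 3; list adjusted p = 0.971). That list's median and mean were negative while its test pointed up. Of 8 cytosolic heat shock genes hsp-12.3, a small heat shock gene, fell (log2 change -0.91 ± 0.17, adjusted p = 0.0127, or 0.0690 without culture replicate 2; list adjusted p = 0.699). Among 105 nuclear hormone receptor genes 2 fell (list adjusted p = 0.531) and among 33 chemoreceptor genes 2 fell (list adjusted p = 0.197). Adjusted over the list alone, the counts were 2 falls for heat shock, 1 rise and 1 fall for DAF-16, 1 rise and 2 falls for chemoreceptors, and as given for the others.

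Lists with no call and no member past the gene test in the 3 main comparisons numbered 11, holding 229 genes: endoplasmic reticulum stress, mitochondrial stress, vitellogenin, propionate shunt, sulfide and cyanide response, osmotic response, central carbon metabolism, synaptic transmission, F-box, oxidative phosphorylation and histone genes. Their medians lay between -0.11 and 0.12 on the log2 scale, and their smallest camera adjusted p was 0.0596. Adjusted over the list alone, 2 of their genes passed in the culture and 0 in August and October (limma; 412 and 286 of all probe sets had an unadjusted p under 0.05 there, where chance gives 676). In the culture the ribosomal protein and proteasome lists did not pass (adjusted p = 0.637 and 0.0804).

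October was compared with August to test whether the lake samples differed from each other. Only cyp-33A1 and fat-7 passed. The former was 10.4-fold lower in October than in August (log2 difference -3.38 ± 0.12, limma adjusted p = 1.70e-10, lower in 3 of 3 arrays). The desaturase gene fat-7 had a log2 difference of -0.81 ± 0.12 (adjusted p = 0.0446, lower in 3 of 3 arrays). The fat-7 call ended under quantile normalization (adjusted p = 0.0877), without August replicate 1 (0.186) or 3 (0.446), and without October replicate 1 (0.227), 2 (0.492) or 3 (0.115), and its lowest value was 0.00101, with the replicate block. Of the lists, 6 were lower in October. All 74 ribosomal protein genes had negative values (median log2 difference -0.12; camera adjusted p = 2.02e-22; adjusted p = 0.671 with an estimated correlation). So did all 5 vitellogenin genes, which encode yolk proteins (median -0.14; adjusted p = 0.00299; adjusted p = 0.671 with an estimated correlation). The other 4 were the proteasome (adjusted p = 0.00166; adjusted p = 0.718 with an estimated correlation), oocyte and eggshell (0.00323; adjusted p = 0.767 with an estimated correlation), P450 (0.0103; adjusted p = 0.525 with an estimated correlation) and fatty acid synthesis lists (0.0191; adjusted p = 0.526 with an estimated correlation). Quantile normalization moved the ribosomal medians against water from 0.079 to 0.0024 in August and from -0.035 to -0.015 in October. It moved the vitellogenin medians from 0.095 to -0.0033 and from -0.063 to -0.041. The lists of October against August were not tested under that scaling, so the size of these differences depends on it. In the P450 and fatty acid synthesis lists 1 gene each fell, cyp-33A1 and fat-7, also when adjusted over the list alone. Neither list was tested without that gene, so these calls may rest on it. In the other 4 lists 0 genes passed either way in limma (350 of all probe sets had an unadjusted p under 0.05, where chance gives 676). With the replicate block, since the rule read these numbers as pairs, 9 lists passed. Those added were higher in October: sperm (adjusted p = 0.00890, against 0.346 without the block), molting (0.0171, against 0.0608) and lysozyme and antimicrobial genes (0.0463, against 0.0763). With the block and an estimated correlation each of these had an adjusted p = 0.555.

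Z-medium was compared with water to give the background between both controls. All 3 probe sets that passed belong to mtl-2, a metallothionein gene whose protein binds metal ions. Its brightest probe set rose from 2240 ± 153 in water to 9200 ± 985 in Z-medium (SD, n = 3; 4.10-fold; log2 change 2.03 ± 0.08; limma adjusted p = 9.99e-10). The other probe sets rose by 2.01 ± 0.09 and 2.36 ± 0.14 on the log2 scale. Its signal in the culture was 4719 ± 186, below Z-medium and above water, and 2188 ± 60.3 and 2065 ± 86.7 in August and October. The fall of mtl-2 in the culture and its rise in Z-medium share the same 3 Z-medium arrays. None of the 38 lists passed (camera; the metal response and iron list had an adjusted p of 0.161, and adjusted p = 0.722 with an estimated correlation). Within that list 1 of 7 genes rose, also adjusted over the list alone, and its median of -0.01 was negative while the mean and the test pointed up. Among named genes that did not pass, the protease gene cpr-1 had a log2 change of 0.29 ± 0.08 and warf-1 one of -0.65 ± 0.17.

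The culture effect minus the mean lake effect tests whether the difference from Z-medium in the culture and the mean difference from water in the lake samples were unequal. The culture was dosed at 40% and the lake samples at 200% of their original AOBr, in different control media. Sample, dose and medium therefore cannot be told apart in it. A gene that changed in the lake samples alone can therefore pass too. It gave 36 probe sets past the test, 13 higher and 23 lower in the culture effect. The difference was 2.54 ± 0.17 for pud-3 (log2 scale, limma adjusted p = 1.79e-06), 2.35 ± 0.27 for pud-4, 1.31 for C50B6.7, 1.29 for irg-4 and 1.11 for sysm-1. It was -1.71 ± 0.16 for cyp-33A1, whose call comes from its August rise of 3.31, with -0.07 in October and -0.09 in the culture. It was -1.70 for ugt-2, with 0.81 in August, 0.77 in October and -0.91 in the culture, and passed in none of these. W08E12.2, F36H12.4 and dpy-9, whose signals fell below the filter in the culture and for F36H12.4 also in water, had differences of -0.89, -1.68 and -0.98 or lower. Of 38 lists 2 were higher and 9 lower, with adjusted p between 0.166 and 0.611 with an estimated correlation. In the gut protease list 3 of 17 genes fell, and 6 adjusted over the list alone (median -0.24; camera adjusted p = 2.25e-06; adjusted p = 0.166 with an estimated correlation). In the lysozyme and antimicrobial list 2 of 38 fell, and adjusted over the list alone 8 fell and 2 rose (median -0.30; adjusted p = 2.21e-05; adjusted p = 0.423 with an estimated correlation). With each of the 15 arrays left out in turn pud-3, pud-4, W08E12.2 and cyp-33A1 stayed past the test, while the other 6 named genes did not in 5 to 13 of the fits (highest adjusted p = 0.155). The count fell to 21 without water replicate 3, and rose to 106 without the 5 replicate 1 arrays and 431 with a term for replicate 1. With replicate number as a block it was 480, 69 higher and 411 lower, or 14.4% higher against 36.1% without the block.

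Fold changes were compared across the 13529 probe sets, which are not independent replicates, for 3 pairs of comparisons. August and October, which share the water arrays, correlated at r = 0.488 (rho = 0.454), against 0.500 in simulated groups with no change that share a control. Their covariance of 0.0141 was not above the simulated 0.0219, whose spread still held the replicate 1 difference. With a term for replicate 1 the simulated covariance was 0.0157, closer to the real value. With 3 water arrays the shared control cannot be split into parts of at least 2 arrays. August and culture, with separate controls, correlated at r = 0.170 (rho = 0.151, jackknife SE 0.522 over arrays), and October and culture at r = 0.0537 (rho = 0.0757, SE 0.445). Of the 209 culture calls, 142 had the same sign in August and 137 in October, with lake medians of -0.08 and -0.05 for those lower in the culture, whose culture median was -0.84. For those higher in the culture (culture median 0.63) the lake medians were -0.02 and 0.03.

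**Figure D3:**
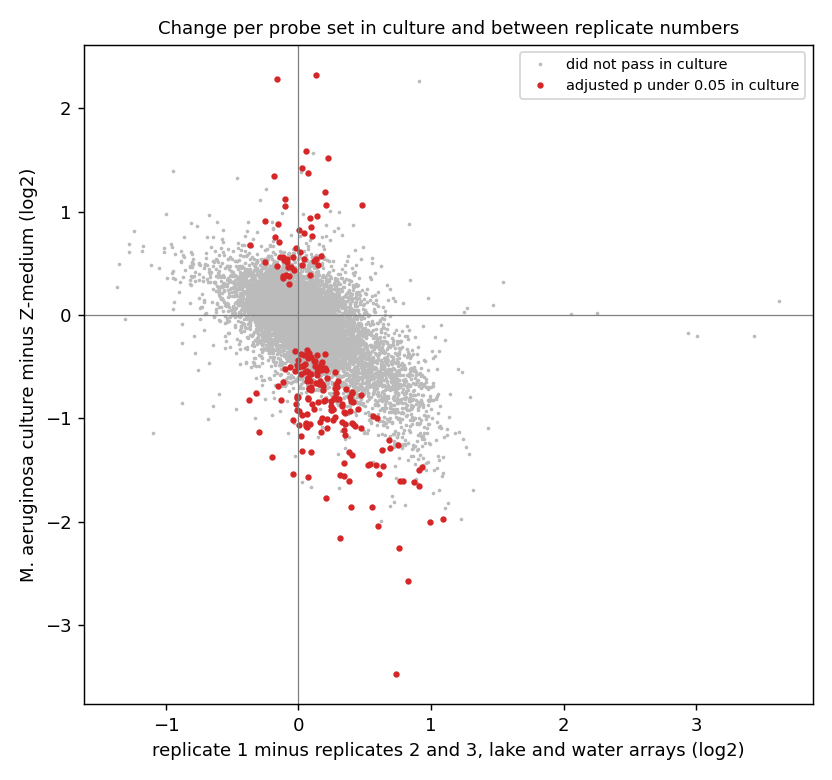
Each point is 1 of 13529 tested probe sets. The vertical axis is the log2 change of the culture against Z-medium and the horizontal axis the log2 difference of replicate 1 from replicates 2 and 3 in the 9 lake and water arrays. Red points passed in the culture (209), and of these 79.4% have opposite signs on the axes (r = -0.604 across all points).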

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

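The tests of other splits of the arrays for August and October, of regroupings within replicate numbers, of reproductive timing, of related transcripts above the filter and of differences among the mtl-2 probe sets were chosen only after the results were seen, as were the fits without the 5 replicate 1 arrays and with position along the replicate 1 difference as a covariate.

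The effects of the lake samples differed from each other for 2 genes by a direct test of the difference (limma), -3.38 on the log2 scale for cyp-33A1 and -0.81 for fat-7, October minus August. The real grouping of these 6 arrays gave more calls than any other (2 against a highest of 0), and was 1 of 10 splits, which are too few for a share under 0.05. For August against water the real value was 1 and the highest other 0, and the same 1 of 10 splits reached it. October against water gave 0 calls in the real split and 0 at most in the others, so that all 10 of 10 reached it. For Z-medium against water the values were 3 and 0, again in 1 of 10 splits. All of these designs have too few splits for a share under 0.05. For August against water, October against August and Z-medium against water, where the numbers were read as pairs, 4 splits part all 3 pairs, the real one included. The others of these, and the 6 that part fewer, gave 0.

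The rise of cyp-33A1 in August was set against 3 technical sources. Median or quantile scaling left it at 3.33 on the log2 scale, where an effect of scaling needed most of the rise to go, and leaving out 1 array left at least 3.24 (highest adjusted p = 1.39e-08), which argues against the scaling and against a single array. Signal from a related transcript was tested on the other 17 probe sets of cyp-33 genes. The 6 of them above the filter rose by at most 0.25, which argues against relatives among those 6, while the largest rise of all, 0.99, came from a dim probe set that went from a signal of 19.6 to 29.3, where a change cannot be told apart from background. A biological response to the August sample, the difference the design names, may stand behind the rise and stays untested. The filtration and lyophilisation are not stated for water, but are described alike for both lake samples, and the October value was -0.07.

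The culture effect differed from the mean lake effect for 36 probe sets by a direct test of the difference (limma). Sample, dose and control medium differ together between these effects and cannot be told apart. The named ones were pud-3 (2.54), pud-4 (2.35), C50B6.7 (1.31), irg-4 (1.29), sysm-1 (1.11), W08E12.2 (-3.33), F36H12.4 (-3.28), cyp-33A1 (-1.71), ugt-2 (-1.70) and dpy-9 (-1.60), all as fitted log2 differences. Those of W08E12.2, F36H12.4 and dpy-9 rest on culture signals below the filter and are -0.89, -1.68 and -0.98 or lower with signals below it set at its level. Among 100 drawn regroupings of the arrays 1, the real one, gave as many, and the highest other gave 3. These put unequal numbers of replicate 1 arrays in a group, unlike the real design. Among 100 that kept 1 array of each number in every group 1, the real one, gave as many, and the highest other gave 27. So many calls were rare under regrouping, which does not exclude chance. Regrouping also moves real group differences into the residual spread, which lowers the counts of the other groupings. For the culture against Z-medium the real split gave 209 and the highest other 0, in 1 of 10 splits, too few for a share under 0.05.

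The culture changes ran opposite to the difference between replicate 1 and replicates 2 and 3 in the lake and water arrays (r = -0.604 across probe sets). A batch of the replicate 1 arrays as the cause was set against fits without them, in which 534 probe sets passed in limma, 174 of the 209 among them. The culture changes thus do not rest on those arrays alone. In these fits 100% of the 209 calls kept their direction at an unadjusted p under 0.05. That share cannot test a batch, since the calls were chosen on a fit that holds the remaining arrays. RNA quality is argued against by the 3' to 5' ratios of the control transcripts, which differed between culture and Z-medium by at most 0.096 ± 0.12 (log2, actin; -0.02 for GAPDH and 0.02 for ubiquitin). A shift in proportion to position along that 1 axis, as the whole cause, is argued against by the covariate. With it 68.9% of the calls (144 of 209) stayed past the test in the same direction. The calls were chosen on the same arrays and the position carries error, so this share may be too high. Culture replicates 2 and 3, at -23.8 and -32.9, lay beyond all other arrays (lowest -19.1). A shift out of proportion to position there was not tested. A difference in reproductive timing between culture and Z-medium worms stays open. The oocyte list moved 0.60 above the sperm list in the culture and to the opposite side in replicate 1 (-0.63), but these values prompted the idea and cannot also test it. Counts of eggs and sperm per worm at collection would show whether reproductive state differed, not why. Developmental stage was not measured, so a difference in timing cannot be told apart from an effect of the culture on growth.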

How the results depend on the processing

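The fits with a term for replicate 1, without the 5 replicate 1 arrays, with the axis covariate and with both the block and an estimated correlation were chosen only after the data were seen, and the cause of a change was not tested unless stated. Counts that moved are grouped by setting. With replicate number as a block, August gave 2, October 2 (drd-10 and warf-1, each adjusted p = 0.0271, up to 1.00 under other settings), the culture 1245, the culture effect minus the lake effect 480 (69 higher and 411 lower), and the lists of October 2, the sperm list added (adjusted p = 0.0124). Where the numbers were read as pairs it changed no call beyond those in the report. With a term for replicate 1 the values were 2, 3, 1201, 431 and 2. Without the replicate 1 arrays the culture gave 534, October against August 5, the culture effect minus the lake effect 106 and the lists of October 4. October gave 1 under median scaling and 1 with array weights. The culture gave 117 when only the compared groups were fitted (fewer residual degrees of freedom) and 461 at an adjusted p under 0.10. October against August gave 1 under quantile normalization, 4 without a filter, 1 without an intensity trend and 1 with only the compared groups. With an estimated correlation the lists of August, October and culture past the test numbered 0, 0 and 0, with the block added 0, 0 and 0, with fry 1, 0 and 3, and under quantile normalization 2 in August and 0 in October.

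With each array left out in turn the counts ranged from 1 to 1 in August, 0 to 0 in October, 89 to 229 in the culture, 1 to 3 for October against August, 3 to 4 for Z-medium against water and 21 to 45 for the culture effect minus the lake effect, and the lists from 3 to 10 in August, 1 to 7 in October and 12 to 15 in the culture. The culture count moved without Z-medium replicate 1 (89) or 2 (92) and without culture replicate 2 (92) or 3 (100), and the culture effect minus the lake effect without water replicate 3 (21). October against August gave 1 without any of its arrays except August replicate 2. The lists of August moved without August replicate 1 (10) and water replicate 3 (7). Those of October moved without water replicates 1 (6) and 3 (7) and October replicates 1 (3), 2 (2) and 3 (7). The 3 correlations of fold changes moved by less than their jackknife error under every setting run. No named gene reversed: of 76 calls 7 were lost under quantile normalization, 13 of the 62 in the culture under median scaling, 6 with an offset of 64 and 42 with at least 1 array left out, and of 127 values that did not pass 31 passed with the block. The fit of only the compared groups was not run for the culture effect minus the lake effect, which uses all 5 groups. Signal over background limits dim probe sets: 9019 below the filter were tested only without it, and the MAS5 values give no background to set against them.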

Other observations

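The tests of reproductive timing and of differences among the mtl-2 probe sets, and the fits without the replicate 1 arrays, were chosen only after the results were seen.

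The difference between replicate 1 and the other replicates had its own gene content in the lake and water groups, where 1454 probe sets passed (limma, 9 arrays). Sperm genes (median log2 difference 0.52), cuticle collagen genes (0.34), molting genes (0.29), osmotic response genes (0.22), cytosolic heat shock genes (0.18) and UDP-glucuronosyltransferase genes (0.15) had higher medians in replicate 1, and germline mitosis and meiosis genes (-0.12), sulfide and cyanide response genes (-0.12) and oocyte and eggshell genes (-0.11) lower ones. These medians were not tested as lists. Sperm are made in larvae and oocytes in adults of this species. On the axis of this difference the replicate 1 arrays of water, Z-medium, August and October stood at 18.5 to 22.6, that of the culture at -11.7, and all replicate 2 and 3 arrays at -6.53 or below, the culture ones lowest at -23.8 and -32.9.

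A hypothesis from these values is that replicate 1 worms were collected slightly earlier in reproductive life than the others, and culture worms slightly later than Z-medium worms. The oocyte minus sperm list medians, 0.60 in the culture and -0.63 in replicate 1, prompted it and cannot also test it, so it may hold and stays open. Collection times within day 1 are not given in the sources used here. Worms of every group staged by hours since the last molt would test it. Counts of eggs and sperm per worm at collection would show whether reproductive state differed, not why.

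The metallothionein gene mtl-2 was higher in Z-medium than in water and lower again in the culture. Cross-hybridisation of a single probe set as the source is argued against by all 3 probe sets, which rose in Z-medium and fell in the culture, with changes that differed among them by at most 0.41 on the log2 scale, in the culture against Z-medium. A related transcript detected by all 3 would give the same agreement, so it cannot be told apart here. A metal load of Z-medium may be the cause, yet its test stays open. The largest rise of mtl-1, cdr-1 and numr-1 was 0.0349 on the log2 scale, in mtl-1, which lay below the filter. numr-1, on a probe set shared with numr-2, changed by -0.18 ± 0.31 at the edge of the filter, and cdr-1 by -0.06 ± 0.20 (SE). By the limits set before the data were seen, fewer than 2 rises over 0.25 counted against the load. That reading was given up after the data were seen, since only cdr-1 lay clear of the filter, so such a load cannot be told apart from its absence.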
